A study of Homo sapiens with 97 samples.

How the data were processed

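RNA sequencing was done on lines of MCF7 and T47D, 2 established breast cancer cell lines that express the estrogen receptor (ER, gene ESR1). Each line is labelled with an ER mutation of the ligand-binding domain, and the series holds 4 of them: MCF7 Y537S, MCF7 Y537N, MCF7 D538G and T47D Y537S. Doxycycline is understood here to induce a mutant ESR1 transgene in them. Full medium is described as DMEM with serum. "White medium" is the name in the labels, which describe it no further than as DMEM with or without estradiol (E2) or doxycycline. Each line had 6 conditions: full medium without or with doxycycline, and white medium alone, with doxycycline, with estradiol, or with both. The labels list 72 RNA samples, of which 69 have a column in the table and 3 do not. Every one of the 24 groups therefore had 3 libraries except MCF7 Y537S in white medium, MCF7 Y537S in white medium with doxycycline and T47D Y537S in full medium with doxycycline, which had 2. The treatment tag of the full medium doxycycline samples reads "none" while their titles name doxycycline. They were grouped by title, and ESR1 followed the titles.

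Per the labels, the RNA reads were aligned to hg19 with STAR 2.5.1, and the deposited gene table was made with Cufflinks 2.2.1. DESeq2 1.1 is also named. The deposited values are taken as FPKM, although the table is titled as counts, because they are fractional and the column sums lie between 673082 and 755091. The table holds 20111 gene symbols, of which 17803 matched a current symbol, and no coordinates. FPKM carries no read counts, so the depth of the RNA libraries is unknown and no counting interval could be given. A relative depth was read from the smallest steps between low values. It ran from 0.669 to 2.57 around a typical library, a ratio of 3.84. Genes at a few FPKM are therefore less precise in the shallower libraries, and the SD of the log2 differences between replicates lay between 0.151 and 0.283 over 66 pairs. KRT8 and KRT18 are listed at 0 in MCF7 Y537N white medium replicate 3, against 13307 and 13298 FPKM for KRT8 and 6103 and 6408 FPKM for KRT18 in the other libraries of that group. These zeros were left as deposited.

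ER binding was measured by ChIP sequencing in 25 lists of peaks, each from 1 library. They came from the same lines in white medium with estradiol, with doxycycline or with both, and from an MCF7 knock-in pair (TALEN in the titles), a parental line and a Y537S clone, in white medium without or with estradiol. For 21 lists the labels name a combination of 2 ER antibodies. For the 4 knock-in lists the labels do not name the antibody. Per the labels, reads were aligned to hg19 with Bowtie, peaks were called with MACS2 (versions not stated), and deepTools 2.2.3 was used. The deposited peak lists give a fold enrichment, which is a ratio, and the significance as -log10 p and -log10 q. The largest listed q lies at or just under 0.01 in each list, so the lists hold only peaks past that limit. The lists held 6584 to 49568 peaks and give no read numbers. For 4 of the 6 MCF7 Y537N records the title and the attached list name different conditions, so their values are given without a comparison.

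Analysis started from these deposited values. Genes with at least 1 FPKM in at least 3 libraries of a line were kept, and log2(FPKM + 1) was fitted with limma 3.58.1 (trend and robust options) in R 4.3.3, with 1 term per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A pseudocount of 1 pulls fold changes of weakly expressed genes toward 0, so these are understated. In each line 6 contrasts were tested: doxycycline in white medium, estradiol in white medium, doxycycline against estradiol, doxycycline with estradiol present, doxycycline in full medium, and the interaction, which is the change with both treatments minus the sum of the separate changes on the log2 scale. Of the 28 comparisons these made up 24. The other 4 tested the difference between lines in the white medium effect of doxycycline, in a fit of both lines. Groups of 2 libraries give wider errors. The titles of the RNA libraries carry a running number and no replicate number, so libraries were not paired. Nothing in the labels says whether replicates are separate cultures, so a p-value here measures a difference against the spread between these samples. In tests on simulated data, 65% of changes of 0.5 and 95% of changes of 1 (log2) were found for doxycycline in MCF7 Y537S, and 85% and 99% in MCF7 Y537N. For the interaction in MCF7 Y537N 48% and 96% were found. The changes were put in 200 genes with a mean log2(FPKM + 1) above 2, fewer genes than were called in the data. These rates therefore do not cover weakly expressed genes.

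A set of 17 gene lists was tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. The lists were estrogen-raised and estrogen-lowered genes, cell cycle, ribosome biogenesis, integrated stress response, unfolded protein response, interferon-stimulated genes, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded mRNAs, epithelial and luminal genes, basal epithelial genes, mesenchymal and migration genes, targets of nuclear receptors other than ER, and markers of fibroblasts, immune cells and endothelium. A list needed 3 tested members. Counts of list members use the adjusted p over all genes tested, and where given, the count adjusted over the list alone. The genes named were set by a rule: for each comparison ESR1, the 6 largest rises and the 6 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 FPKM and no overlap between the libraries compared, and up to 4 members of each list described, which are the 3 called members with the largest change and the most highly expressed member not called. A subset of these genes is printed. The groups, comparisons, tests, lists and this rule were chosen before the data were examined. The count-based tests planned for a count table were replaced by the limma fit planned for FPKM.

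For MCF7 Y537S, the line with 3 lists per condition, peak numbers were compared by exact two-sided permutation tests of mean log2 numbers, 3 lists against 3, where 0.1 is the smallest p possible. Lists sharing a replicate number also shared a title code. The presence of each region, taken as its deviation from the mean of the condition, correlated at 0.144 to 0.545 between lists with the same number and at -0.348 to 0.148 between others, and the best partner of each of the 9 lists had its own number. Within each other condition taken alone this held for 7 of the 9. Numbers 1 and 2 share a title code, and between these numbers the correlations were 0.11 to 0.148. Number 3, which the titles do not give, has another code, and its lists correlated with theirs at -0.348 to -0.217. The correlations thus separate the codes more clearly than numbers 1 and 2. The lists were also compared as blocks of pairs with an exact sign-flip test, where the smallest p possible is 0.25. Consensus regions were merged from peaks overlapping by at least 1 bp and kept when present in at least 2 lists of a condition. The count of overlapping peaks for a pair of lists was checked with bedtools 2.31.1. For single lists the overlapping percentage of peaks is given with a 95% Wilson interval, which covers counting error only. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for peaks and plots. A comparison of changed genes with nearby ER sites was planned and not made, since the annotation given is of GRCh38.p14 while the peaks are on hg19. That annotation was not used here for peaks.

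The alternatives were median-of-ratios and column-sum scaling in place of the scale as deposited, a pseudocount of 0.1, no filter on low values, both together, an added requirement of an absolute log2 change of 1, fits of only the libraries compared or of all RNA libraries, leaving out each library in turn, other list tests, other overlap rules and a stricter peak limit. Column-sum scaling moves the median change of all genes to between -0.199 and 0.204 over the 28 comparisons, so small changes shared by many genes depend on the scaling. No line without a transgene was sequenced, so effects of doxycycline itself cannot be separated from those of the induced receptor.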

Results

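Gene expression was measured by RNA sequencing in 4 breast cancer lines carrying a doxycycline-responsive mutant ER: MCF7 Y537S, MCF7 Y537N, MCF7 D538G and T47D Y537S. The 69 libraries fell into 24 groups of line and condition, with 3 libraries in each apart from the 3 groups that held 2. ER binding was measured by ChIP sequencing as 25 lists of peaks from these lines and from an MCF7 knock-in pair. Expression levels are given as mean FPKM ± SD over the libraries of a group, and changes as log2 fold change ± SE. The table gives no read counts, and column sums of FPKM lay between 673082 and 755091. A gene named below with a rise or a fall between 2 groups was higher, or lower, in every library of one group than in every library of the other.

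ESR1, the gene of ER itself, was measured first, since it reports on the induction in each library. In white medium it rose with doxycycline in all 4 lines: from 47.9 ± 2.0 to 1131 ± 38.5 FPKM in MCF7 Y537S (n = 2 and 2), from 49.4 ± 6.65 to 2247 ± 68.6 in MCF7 Y537N (n = 3 and 3), from 41.3 ± 3.94 to 735.1 ± 49.5 in MCF7 D538G, and from 130.2 ± 24.5 to 737.3 ± 34.2 in T47D Y537S. The log2 changes were 4.53 ± 0.13 (adjusted p = 1.15e-12), 5.49 ± 0.11 (adjusted p = 4.98e-16), 4.12 ± 0.097 (adjusted p = 1.31e-14) and 2.51 ± 0.12 (adjusted p = 7.42e-11). In full medium the rises were 4.01, 3.95, 2.64 and 4.05 in the same order. Estradiol alone lowered ESR1 in T47D Y537S, to 29.8 ± 1.59 FPKM (log2 change -2.07 ± 0.12, adjusted p = 2.68e-09). In the MCF7 lines its log2 change with estradiol was 0.0031 (Y537S, adjusted p = 0.989), -0.15 (Y537N, adjusted p = 0.33) and -0.18 (D538G, adjusted p = 0.164). The induction in white medium was larger in MCF7 Y537N than in the other MCF7 lines, with a difference of -0.96 for Y537S minus Y537N (adjusted p = 0.000719) and of 1.36 for Y537N minus D538G (adjusted p = 9.67e-08). Reads of the transgene and of the cells' own gene are not separated in these values.

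**Figure D1:**
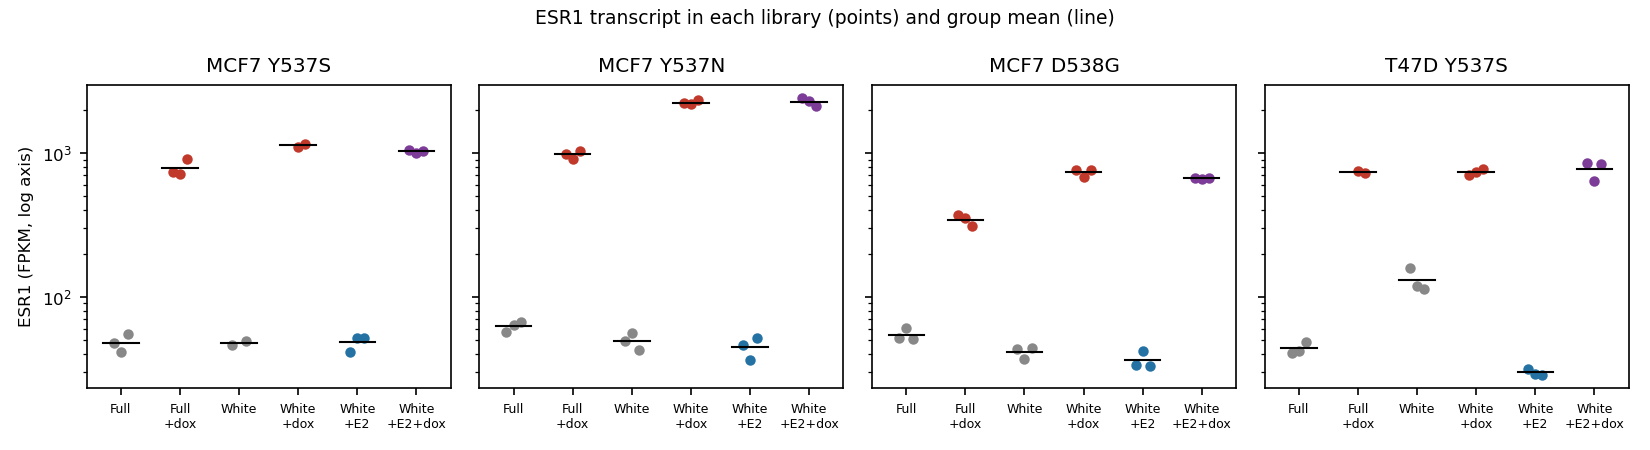
ESR1 in FPKM (log axis) for each RNA library (points) with the group mean (line), by line and condition. In white medium the group means with doxycycline lie between 668.9 and 2277 FPKM, and those without it between 29.8 and 130.2 FPKM.

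Doxycycline in white medium asks which genes change when the mutant receptor is induced without added estradiol. In MCF7 Y537S (n = 2 and 2), genes of the estrogen-raised list rose, and genes of the estrogen-lowered list fell. PKIB, an inhibitor of protein kinase A, rose from 7.21 ± 0.326 to 122.2 ± 4.89 FPKM (log2 change 3.91 ± 0.11, adjusted p = 1.02e-12), and CXCL12, a chemokine, from 5.85 ± 0.386 to 68.1 ± 4.63 FPKM (3.33 ± 0.1). NPPC, the C-type natriuretic peptide, went from 0.264 ± 0.0759 to 49.5 ± 4.14 FPKM and ANXA9, an annexin, from 45.6 ± 0.345 to 840.0 ± 132 FPKM (4.17 ± 0.087, adjusted p = 2.5e-14). ACKR3, a scavenging receptor for CXCL12, fell from 77.2 ± 4.9 to 8.90 ± 2.69 FPKM (-3.01 ± 0.16), PSCA, a cell surface antigen, from 58.3 ± 0.292 to 6.98 ± 1.32 FPKM, and AQP3, a water and glycerol channel, from 27.9 to 3.34 FPKM. Of 45 estrogen-raised genes, 31 rose and 6 fell, the same counts as when adjusted over the list alone (list test adjusted p = 5.75e-16). CTSD, the most highly expressed member that was not called, was at 286.1 and 280.9 FPKM. Of 18 estrogen-lowered genes 13 fell and 2 rose (adjusted p = 1.15e-07), among them BMF, which promotes apoptosis, from 35.0 to 5.52 FPKM. That list's value was adjusted p = 0.132 with an estimated correlation. In all, 1916 genes were raised and 2293 lowered of 12247 tested.

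Cell cycle genes in MCF7 Y537S did not rise with doxycycline in white medium, and 16 of 43 fell (adjusted p = 0.000327, and adjusted p = 0.611 with an estimated correlation). CDT1, which licenses replication origins, fell from 50.7 ± 3.37 to 29.9 ± 3.34 FPKM (log2 change -0.75 ± 0.12, adjusted p = 0.000158), while MCM7 was at 111.6 and 89.3 FPKM and was not called (adjusted p = 0.138). Of 21 interferon-stimulated genes 13 fell, such as IFI44 (-1.39), BST2 (-1.18) and OAS1 (-1.14), with adjusted p = 0.000166 for the list and adjusted p = 0.257 with an estimated correlation. Of 20 ribosome biogenesis genes 7 rose (adjusted p = 0.0114, and adjusted p = 0.257 with an estimated correlation).

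In MCF7 Y537N and MCF7 D538G (n = 3 and 3), NPPC and PKIB also rose with doxycycline in white medium, and IGFBP5 and AQP3 fell. In Y537N, NPPC rose from 0.742 ± 0.166 to 38.9 ± 3.68 FPKM, ANXA9 from 49.2 ± 2.13 to 915.8 ± 41.3 FPKM (log2 change 4.19 ± 0.057, adjusted p = 3.59e-18) and PKIB from 12.4 ± 1.29 to 103.6 ± 3.41 FPKM (2.96 ± 0.071). IGFBP4, which binds insulin-like growth factors, rose from 62.1 ± 3.47 to 355.4 ± 19.9 FPKM, while IGFBP5 fell from 21.1 ± 0.95 to 2.64 ± 0.0339 FPKM and AQP3 from 46.6 ± 1.12 to 4.98 ± 0.106 FPKM (-2.99 ± 0.081). In D538G, NPPC rose from 0.710 ± 0.273 to 40.9 ± 5.12 FPKM, CENPT, a centromere protein, from 19.3 ± 0.229 to 223.8 ± 19.9 FPKM (3.46 ± 0.061, adjusted p = 2.18e-16), and PKIB from 8.95 ± 0.306 to 38.3 ± 2.39 FPKM (1.98 ± 0.059). IGFBP5 fell there from 23.8 ± 1.71 to 2.14 ± 0.822 FPKM (-3.01 ± 0.14). Of the estrogen-raised genes 32 of 45 rose and 6 fell in Y537N (adjusted p = 2.16e-15), and 28 of 44 rose and 4 fell in D538G (adjusted p = 1.96e-21), where the counts adjusted over the list alone were 33 and 5. Of 18 estrogen-lowered genes 16 fell and 1 rose in Y537N (adjusted p = 6.5e-09, and adjusted p = 0.0542 with an estimated correlation), and 15 fell and 0 rose in D538G (adjusted p = 3.46e-15). Called genes numbered 2529 raised and 3979 lowered in Y537N, and 1085 raised and 1407 lowered in D538G. The split in Y537N depends on the scaling: 38.9% of called genes were raised as deposited, 50.2% with median-of-ratios scaling and 24.7% with column-sum scaling. A fit of only the compared libraries called 1608 genes in D538G.

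The cell cycle list did not pass its test with doxycycline in white medium in Y537N (5 of 43 rose and 16 fell, adjusted p = 0.695) or in D538G (4 rose and 11 fell, adjusted p = 0.319). In Y537N, MYBL2, a transcription factor of cycling cells, rose from 64.8 to 130.8 FPKM while CCNE2, a cyclin, fell by 0.852 on the log2 scale. Interferon-stimulated genes fell in both lines: 14 of 16 in Y537N (adjusted p = 0.00596, and adjusted p = 0.172 with an estimated correlation) and 15 of 21 in D538G (adjusted p = 5.13e-08, and adjusted p = 0.134 with an estimated correlation). Across the 3 MCF7 lines, 644 genes were raised and 822 lowered in all of them, of 12021 tested in all 3. Of those also tested in T47D Y537S, 338 of 604 were raised and 364 of 738 lowered there too. For Y537S and D538G together, 686 genes were raised in both where 165.1 would share that call by chance, and 52 had opposite calls. For MCF7 Y537S and T47D Y537S 765 were raised and 816 lowered in both (chance 431.7 and 442.2), and 658 had opposite calls. For Y537N and T47D Y537S these were 968 and 1156 (chance 581.2 and 775.1), with 956 opposite. No chance number was computed for opposite calls, so their counts do not show discordance between lines.

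In T47D Y537S (n = 3 and 3) all 44 tested members of the estrogen-raised list rose with doxycycline in white medium (adjusted p = 3.97e-33). TFF1, a secreted trefoil peptide and classical ER target, rose from 4.43 ± 0.758 to 29.97 ± 2.04 FPKM (log2 change 2.52 ± 0.16, adjusted p = 2.39e-09), PDZK1, a scaffold protein, from 4.29 ± 0.596 to 32.9 ± 0.675 FPKM, NPY1R, a neuropeptide Y receptor, from 8.01 ± 0.882 to 56.6 ± 9.31 FPKM, and PRSS23, a serine protease, from 16.9 ± 2.33 to 88.9 ± 6.23 FPKM. UPK2, a uroplakin, fell from 48.6 ± 1.58 to 3.01 ± 0.785 FPKM (-3.65 ± 0.16, adjusted p = 4.35e-11), SOD3, the extracellular superoxide dismutase, from 278.4 ± 25.6 to 40.9 ± 4.39 FPKM, and IL1R1, the interleukin 1 receptor, from 26.9 ± 1.76 to 4.21 ± 0.485 FPKM. Of 18 estrogen-lowered genes 15 fell and 1 rose (adjusted p = 4.85e-09). Cell cycle genes rose, 27 of 43 with 2 falling (adjusted p = 7.09e-06, and adjusted p = 0.274 with an estimated correlation), as PLK1, a mitotic kinase, did from 39.1 ± 3.24 to 70.0 ± 4.26 FPKM and CCNB1 from 128.0 to 218.5 FPKM. Of 20 ribosome biogenesis genes 15 rose (adjusted p = 0.000405, and adjusted p = 0.27 with an estimated correlation), MYC among them from 5.70 to 14.8 FPKM. Of 20 interferon-stimulated genes 11 fell and 2 rose (adjusted p = 0.00743, and adjusted p = 0.274 with an estimated correlation). In all, 3211 genes were raised and 2675 lowered of 12643.

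Estradiol in white medium shows the response to the ligand in the same cells without doxycycline. Known ER targets rose in the MCF7 lines. GREB1, a cofactor of ER, rose from 16.9 ± 4.49 to 173.7 ± 13.7 FPKM in MCF7 Y537S (n = 2 and 3, log2 change 3.31 ± 0.12, adjusted p = 2.52e-11), from 16.8 ± 1.79 to 136.5 ± 3.38 FPKM in Y537N (2.95) and from 17.3 ± 1.45 to 146.3 ± 3.27 FPKM in D538G (3.01). TFF1 rose from 177.7 ± 22.8 to 1555 ± 72.2 FPKM in Y537S and from 299.5 ± 31.8 to 1898 ± 65.1 FPKM in D538G. PSCA fell in all 3 MCF7 lines (-2.27, -2.22 and -1.88). In T47D Y537S, CXCL12 rose from 13.9 ± 2.66 to 134.5 ± 9.0 FPKM (3.20 ± 0.092, adjusted p = 1.38e-12), STC2, a secreted stanniocalcin, from 23.6 ± 1.44 to 149.9 ± 10.3 FPKM and MYC from 5.70 ± 0.405 to 25.9 ± 1.16 FPKM. The estrogen-raised list rose in 42 of 45, 43 of 45, 42 of 44 and 33 of 44 members in MCF7 Y537S, Y537N, D538G and T47D Y537S (adjusted p = 9.09e-47, 1.57e-44, 2.17e-44 and 5.14e-17), with 1 member falling in T47D. The estrogen-lowered list fell in 15, 17, 17 and 16 of 18 (adjusted p = 5.65e-12, 1.59e-14, 4.04e-16 and 1.19e-07). Both lists passed with an estimated correlation in every line.

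Cell cycle genes rose with estradiol in white medium in each line, 33, 38, 40 and 42 of 43 in the same order, and none fell. The list tests gave adjusted p = 6.73e-20, 1.39e-29, 4.07e-28 and 3.3e-25, and in MCF7 Y537S adjusted p = 0.163 with an estimated correlation. MYBL2 rose from 65.0 ± 5.58 to 161.4 ± 12.3 FPKM in MCF7 Y537S, from 64.8 to 160.1 FPKM in Y537N and from 78.5 to 184.0 FPKM in T47D, and RRM2, a subunit of ribonucleotide reductase, from 63.2 to 137.8 FPKM in Y537N. CCNB1 in MCF7 Y537S was at 85.8 and 87.9 FPKM (adjusted p = 0.884). Ribosome biogenesis genes rose in 19 of 20 members in T47D (adjusted p = 7.36e-12), and in 8, 8 and 11 members in MCF7 Y537S, Y537N and D538G (adjusted p = 4.26e-05, 0.00495 and 6.61e-05). In the MCF7 lines these were adjusted p = 0.0975, adjusted p = 0.268 and adjusted p = 0.0697 with an estimated correlation. Raised and lowered genes numbered 1391 and 1893 in MCF7 Y537S, 1756 and 2061 in Y537N, 1860 and 2067 in D538G, and 2731 and 3725 in T47D. In MCF7 Y537S the count of called genes fell to 1558 without white medium replicate 3, which left 1 library in that group, and with median-of-ratios scaling the share raised went from 42.4% to 53.5%. In Y537N column-sum scaling took that share from 46.0% to 27.7%.

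Doxycycline and estradiol changed many of the same genes in the same direction. In MCF7 Y537S 415 genes were raised and 785 lowered by both, where 217.6 and 354.4 would be by chance, and 411 went opposite ways. For the opposite ones no chance number was computed. In Y537N 642 were raised by both and 1219 lowered by both (chance 360.3 and 665.3), in D538G 365 and 728 (chance 163.9 and 236.2), and in T47D 1441 and 1526 (chance 693.6 and 788.1). Both comparisons share the white medium libraries, which alone gives a positive covariance of the log2 changes. The observed covariances were 0.0704, 0.073, 0.0392 and 0.0822, against 0.0141, 0.00902, 0.00832 and 0.00865 in simulated unchanged groups. The correlations were 0.355, 0.416, 0.404 and 0.437, below the 0.55, 0.487, 0.505 and 0.493 of the simulated groups, so the correlation does not set the shared response apart from the shared libraries. With the estradiol effect of another line, which shares no library, 280 genes were raised in both and 521 lowered in both for doxycycline in D538G and estradiol in MCF7 Y537S (chance 122.7 and 211.1). For doxycycline in MCF7 Y537S and estradiol in T47D these numbers were 512 and 741 (chance 395.4 and 612.2), and for D538G and estradiol in T47D 296 and 490 (chance 228.5 and 360).

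**Figure D2:**
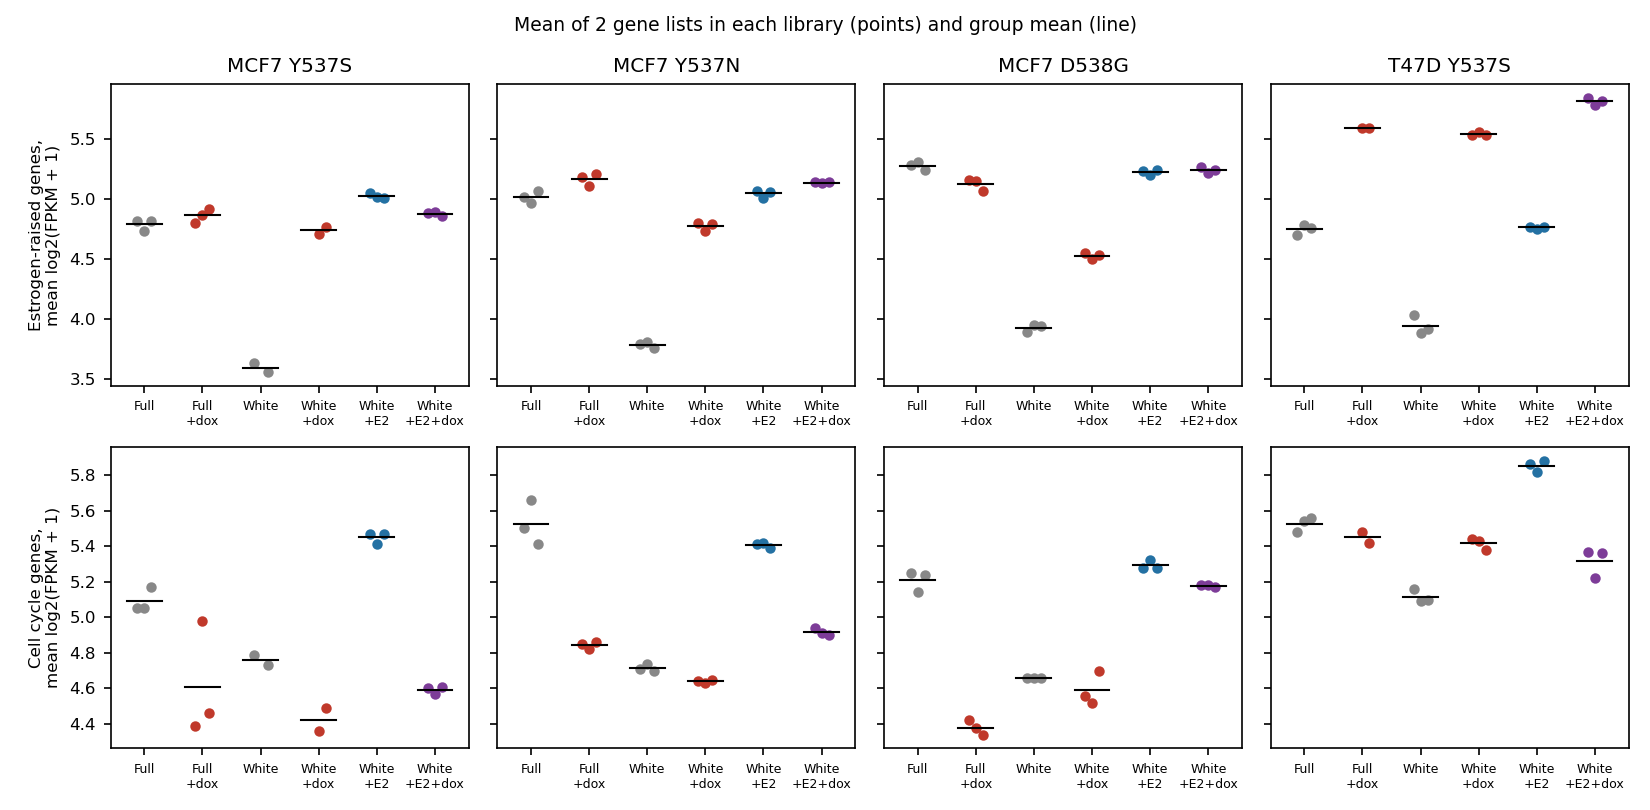
Mean log2(FPKM + 1) of the estrogen-raised and the cell cycle lists in each RNA library (points) with the group mean (line), by line and condition. In white medium the cell cycle list was lower with doxycycline than with estradiol in all 4 lines, by list means of -1.02, -0.77, -0.70 and -0.44 in the order MCF7 Y537S, Y537N, D538G and T47D Y537S.

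Doxycycline against estradiol in white medium sets the induced receptor without added ligand directly against the ligand. Cell cycle genes were lower with doxycycline in every line: 38 of 43 in MCF7 Y537S and in Y537N, 40 of 43 in D538G and 29 of 43 in T47D, where 2 were higher. CDT1 was at 29.9 FPKM with doxycycline and 109.9 with estradiol in MCF7 Y537S (log2 difference -1.85), and at 35.2 and 96.3 in Y537N (-1.43), and CDC45, a replication helicase factor, was at 12.1 and 28.4 FPKM in D538G (-1.18). In T47D, E2F1 was at 27.1 and 53.8 FPKM (-0.97). The list tests gave adjusted p = 8.92e-18, 5.34e-15, 3.88e-25 and 2.26e-10. With an estimated correlation D538G kept its call (adjusted p = 0.0117), and the others were adjusted p = 0.371, adjusted p = 0.151 and adjusted p = 0.104 with an estimated correlation in MCF7 Y537S, Y537N and T47D.

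ER targets moved apart in this comparison. TFF1 was lower with doxycycline than with estradiol in the MCF7 lines: 299.3 ± 38.3 against 1555 FPKM in Y537S (log2 difference -2.38, adjusted p = 2.51e-10), 323.3 ± 39.1 against 2250 ± 69.9 in Y537N (-2.80) and 149.4 ± 13.6 against 1898 in D538G (-3.66 ± 0.092). In D538G its mean with doxycycline also lay below that in white medium alone, given above. TFF1 was higher with doxycycline than with estradiol in T47D Y537S, 29.97 against 4.78 ± 1.58 FPKM (2.45, adjusted p = 5.1e-09). RAMP3, a receptor activity modifier, and WISP2, a secreted protein of the CCN family, were lower in MCF7 Y537S (-3.28 and -2.66) and Y537N (-2.50 and -2.75). NPPC (5.24) and ANXA9 (4.34) were higher in MCF7 Y537S, and CAPN8, a calpain, went from 1.32 to 28.5 FPKM in T47D. Of the estrogen-raised list 33 of 44 members were lower in D538G and 2 higher (adjusted p = 1.45e-14). In T47D 31 of 44 were higher and 8 lower (adjusted p = 7.36e-07, and adjusted p = 0.104 with an estimated correlation). In MCF7 Y537S 15 were higher and 24 lower (adjusted p = 0.0768), and in Y537N 15 and 20 of 45 (adjusted p = 0.66). Higher and lower genes numbered 2921 and 2664 in MCF7 Y537S, 2623 and 3665 in Y537N, 2091 and 2273 in D538G, and 3698 and 2797 in T47D.

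Doxycycline with estradiol present asks what the induced receptor adds to the ligand. In MCF7 Y537S (n = 3 and 3), ESR1 rose by 4.39 ± 0.11, HSD17B11, a steroid dehydrogenase, from 4.24 to 95.7 FPKM (4.23 ± 0.18) and ITIH2 from 0.163 to 16.0 FPKM. THBS1, a matrix glycoprotein, fell from 72.5 to 10.3 FPKM (-2.71), as did GFRA1, a receptor for glial cell line-derived neurotrophic factor (-2.60), and WISP2 (-2.40). In Y537N, ANXA9 rose from 50.5 to 1561 FPKM (4.92 ± 0.057), and KRT80, a keratin, fell from 298.6 to 51.3 FPKM. TFF1 fell from 2250 to 577.6 FPKM there (-1.96) and from 1898 to 461.4 FPKM in D538G (-2.04), while in T47D it rose from 4.78 to 47.8 FPKM (3.10). UPK2 in T47D fell from 32.8 to 1.07 FPKM (-4.02) and SOD3 from 191.6 to 19.0 FPKM (-3.26).

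With estradiol present, doxycycline lowered cell cycle genes in each line: 35 of 43 in MCF7 Y537S (adjusted p = 1.33e-13, and adjusted p = 0.492 with an estimated correlation), 31 in Y537N (adjusted p = 1.31e-08, and adjusted p = 0.213 with an estimated correlation), 18 in D538G with 5 rising (adjusted p = 0.0112, and adjusted p = 0.488 with an estimated correlation) and 34 in T47D (adjusted p = 7.62e-13, and adjusted p = 0.0757 with an estimated correlation). CDT1 fell in MCF7 Y537S from 109.9 to 31.0 FPKM (-1.79), and CCNE1, cyclin E1, in T47D from 10.1 to 3.93 FPKM (-1.16). The estrogen-raised list rose in T47D, in 34 of 44 members with 2 falling (adjusted p = 3.55e-15). It did not pass in the MCF7 lines, where 15 rose and 21 fell in Y537S (adjusted p = 0.264), 21 rose and 15 fell in Y537N (adjusted p = 0.251), and 18 rose and 12 fell in D538G (adjusted p = 0.423). Genes of the integrated stress response fell in the MCF7 lines, in 15, 13 and 14 of 19 (adjusted p = 5.8e-05, 0.000124 and 7.11e-07), and rose in T47D in 16 of 21 (adjusted p = 0.000368). The respective values were adjusted p = 0.492, adjusted p = 0.377, adjusted p = 0.3 and adjusted p = 0.286 with an estimated correlation. Estradiol alone had raised this list, in 9, 11 and 9 of 19 in the MCF7 lines and 15 of 21 in T47D. Those list tests gave adjusted p = 6.34e-06, 4.8e-06, 0.000177 and 2.21e-06, and 0.371, 0.33, 0.404 and 0.18 with an estimated correlation. The falls in the MCF7 lines therefore started from a level raised by estradiol. Cholesterol synthesis genes fell in T47D, in 16 of 19 (adjusted p = 4.25e-07), and rose in MCF7 Y537S, in 12 of 19 (adjusted p = 0.00136, and adjusted p = 0.492 with an estimated correlation). Raised and lowered genes numbered 3238 and 2883 in MCF7 Y537S, 3224 and 3187 in Y537N, 2074 and 1732 in D538G, and 3234 and 2943 in T47D.

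Doxycycline in full medium shows induction in medium with serum. In MCF7 Y537S (n = 3 and 3), HMGCS2, the rate-limiting enzyme of ketone body synthesis, rose from 0.0615 to 34.9 ± 4.76 FPKM (log2 change 5.07 ± 0.14) and CEACAM6, a cell adhesion protein, from 9.90 ± 0.908 to 189.2 ± 33.8 FPKM (4.11). NPPC rose in all 3 MCF7 lines (4.76, 4.54 and 5.34). THBS1 fell in them, from 84.3 ± 6.22 to 11.3 ± 1.28 FPKM in Y537S (-2.79), from 36.1 ± 4.21 to 10.1 ± 0.216 in Y537N (-1.74) and from 61.9 ± 6.02 to 17.99 ± 0.89 in D538G (-1.72). In T47D (n = 3 and 2), PRSS23 rose from 8.00 to 63.8 FPKM (2.84) and WISP2 from 0.595 to 9.05 FPKM (2.66). MYC, a growth-promoting transcription factor, fell in the MCF7 lines, from 113.0 ± 3.41 to 45.5 ± 3.49 FPKM in Y537S (-1.30), from 49.5 to 30.5 in Y537N and from 84.3 to 48.7 in D538G. TOP2A, a topoisomerase, fell from 71.7 ± 5.36 to 31.3 ± 1.47 FPKM in Y537S, and MCM5, a replication helicase subunit, from 79.0 ± 7.78 to 26.2 ± 1.85 FPKM in D538G (-1.55).

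Cell cycle genes fell in full medium in 30 of 43 in MCF7 Y537S with 1 rising (adjusted p = 6.06e-05, and adjusted p = 0.639 with an estimated correlation), in 42 in Y537N (adjusted p = 3.22e-20, and adjusted p = 0.0594 with an estimated correlation) and in all 43 in D538G (adjusted p = 1.82e-24). In T47D 9 rose and 10 fell (adjusted p = 0.56). In MCF7 Y537S replicate 2 with doxycycline stood apart in this list, with a list mean of 4.98 against 4.39 and 4.46 log2(FPKM + 1) in the other doxycycline libraries, and also in the integrated stress response list (5.02 against 5.78 and 5.82). Ribosome biogenesis genes fell in 17, 17 and 19 of 20 in the MCF7 lines and in 7 in T47D (adjusted p = 6.06e-05, 3.41e-07, 4.47e-08 and 0.0198). D538G kept that call, and the others were adjusted p = 0.227, adjusted p = 0.078 and adjusted p = 0.429 with an estimated correlation in MCF7 Y537S, Y537N and T47D. Estrogen-raised genes rose in T47D, in 32 of 44 with 1 falling (adjusted p = 1.05e-21), and in Y537N in 21 of 45 with 13 falling (adjusted p = 0.0281, and adjusted p = 0.534 with an estimated correlation). In MCF7 Y537S 17 rose and 15 fell, with a list median of -0.038 and a mean of 0.074 (adjusted p = 0.36), and in D538G 9 rose and 14 fell (adjusted p = 0.577). Raised and lowered genes numbered 2890 and 4040 in MCF7 Y537S, 2296 and 2866 in Y537N, 2043 and 3070 in D538G, and 1757 and 2352 in T47D. In T47D the count of called genes, 4109, was 2245 without full medium doxycycline replicate 3, which left 1 library there. With median-of-ratios scaling the share raised in T47D went from 42.8% to 53.0%.

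The interaction asks whether both treatments together change a gene by more or less than the sum of their separate log2 changes. For estrogen-raised genes the joint change fell short of that sum in all 4 lines. CXCL12 did so in each (interaction -3.23 in MCF7 Y537S with adjusted p = 8.81e-10, -2.04 in Y537N, -1.65 in D538G and -2.46 in T47D), and GREB1 in MCF7 Y537S (-2.82) and Y537N (-2.35). EPAS1, a hypoxia-inducible transcription factor, had a positive interaction in MCF7 Y537S (1.95) and Y537N (1.70). In T47D MYC (-1.99), STC2 (-2.15) and AURKB, a mitotic kinase (-1.31), had negative interactions, and ESR1 a positive one (2.14, adjusted p = 6.93e-07). With doxycycline ESR1 in T47D was at 737.3 ± 34.2 FPKM without estradiol and 778.1 ± 122 FPKM with it. Its positive interaction therefore goes with its fall under estradiol alone, from 130.2 to 29.8 FPKM. The list means of estrogen-raised genes were -1.29, -0.90, -0.59 and -0.55, with 34 of 45, 35 of 45, 22 of 44 and 25 of 44 members called negative and 0, 0, 1 and 3 positive (adjusted p = 1.28e-47, 1.05e-27, 7.04e-30 and 2.82e-11). Each of these passed with an estimated correlation. In T47D 41 of 43 cell cycle genes (list mean -0.84, adjusted p = 5.34e-34) and 15 of 20 ribosome biogenesis genes (-0.68, adjusted p = 1.28e-12) were called negative.

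Of the genes that both treatments changed in the same direction, 630 of 1200 had a called interaction in MCF7 Y537S, 1165 of 1861 in Y537N, 254 of 1093 in D538G and 1679 of 2967 in T47D. Choosing genes by both effects favours such calls, since the white medium libraries enter both effects and the interaction. Interactions were called in 1444 genes in MCF7 Y537S (811 positive, 633 negative), 4422 in Y537N (2728 and 1694), 735 in D538G (448 and 287) and 3335 in T47D (1590 and 1745). The count in MCF7 Y537S was 539 without white medium replicate 3 and 811 without white medium doxycycline replicate 3. In D538G, leaving out a library moved it to 457, 484 and 461 (white medium replicates 1, 2 and 3), 430 and 1166 (doxycycline replicates 1 and 3), 368 and 463 (estradiol replicates 1 and 2) and 456 and 412 (both treatments, replicates 1 and 2). The share of positive interactions also moved with scaling: in MCF7 Y537S from 56.2% to 43.1% with median-of-ratios scaling, in Y537N from 61.7% to 47.4% with that scaling and 79.4% with column sums, in D538G from 61.0% to 43.2% and 71.4%, and in T47D from 47.7% to 58.0% with column sums.

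Differences between lines in the white medium effect of doxycycline compare lines with different mutations, and for T47D a different cell background. Each mutation in MCF7 comes from a single line, so it cannot be told apart from other differences between the lines. The differences are signed, so a gene said to respond less had the lower log2 change, which can be a fall. The estrogen-raised list responded more in MCF7 Y537S than in D538G, in 26 of 45 members with 7 responding less (list mean 0.56, adjusted p = 1.71e-10), and more in Y537N than in D538G, in 23 with 3 responding less (0.41, adjusted p = 3.72e-15). Between MCF7 Y537S and Y537N 16 were higher and 10 lower (adjusted p = 0.148). Of the estrogen-lowered genes, 11 of 18 fell further in Y537N than in D538G (-0.58, adjusted p = 8.1e-08). CXCL12 responded more in MCF7 Y537S than in D538G, by 1.98, and ANXA9 more in Y537N than in D538G, by 2.40 (adjusted p = 8.46e-15). IGFBP4 responded less in MCF7 Y537S than in Y537N (-2.35, adjusted p = 4.41e-14), as did ACSS1, an acetyl-CoA synthetase (-2.46). The ESR1 induction was larger in Y537N than in D538G, by 1.36. For MCF7 Y537S minus D538G its difference was 0.41 and not called (adjusted p = 0.108), which does not show equal induction. The amount of receptor and its mutation are therefore not separated.

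Between MCF7 Y537S and T47D Y537S, which carry the same mutation, NPPC responded more in MCF7 (5.32), as did PKIB (2.25) and CEACAM6 (3.91). Negative differences were found for OLFM1, olfactomedin 1 (-2.81), WISP2 (-2.78) and CDT1 (-1.32). CDT1 itself fell in MCF7 Y537S, as given above, so its difference is not a weaker rise there. Of 43 cell cycle genes 30 were lower in this difference and 0 higher (adjusted p = 2.8e-08, and adjusted p = 0.557 with an estimated correlation). The estrogen-raised list gave 13 higher and 24 lower (adjusted p = 0.0605). In MCF7 the ESR1 induction was larger, by 2.02. Part of this lies in the level without doxycycline, 47.9 FPKM in MCF7 Y537S and 130.2 in T47D, against 1131 and 737.3 FPKM with it. Called genes numbered 1997 for MCF7 Y537S minus D538G (958 positive, 1039 negative), 1169 for Y537S minus Y537N (661 and 508), 2140 for Y537N minus D538G (914 and 1226) and 4662 for MCF7 Y537S minus T47D (2031 and 2631). The count for Y537S minus Y537N was 617 without white medium doxycycline replicate 2 of MCF7 Y537S, 684 without its white medium replicate 1 and 730 in a fit of only the compared libraries. The share positive moved from 56.5% to 66.6% with column sums there, and for Y537N minus D538G from 42.7% to 58.2% with median-of-ratios scaling and 26.2% with column sums.

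ER ChIP sequencing asks where the receptor binds in white medium with estradiol, with doxycycline, or with both. In MCF7 Y537S the lists with doxycycline were longer. With estradiol they held 25794 ± 3484 peaks (SD, n = 3), with doxycycline 41455 ± 5560 and with both 42008 ± 6549. The difference of the mean log2 peak numbers was 0.69 for doxycycline over estradiol (exact p = 0.1) and 0.70 for both over estradiol (exact p = 0.1), where 0.1 is the smallest p that 3 against 3 allows, and 0.017 for both over doxycycline (exact p = 1). Every list with doxycycline was longer than every list with estradiol alone. In blocks of pairs by replicate number the exact sign-flip test gave p = 0.25, the smallest it allows, for each of the first 2 ratios, and p = 1 for the other. Within the title code of 2 lists per condition the ratios were 0.76, 0.85 and 0.096, and within the code of 1 list per condition 0.54, 0.40 and -0.14. For peaks in the upper part of the pooled q values they were 0.53 (exact p = 0.2), 0.47 (exact p = 0.2) and -0.057 (exact p = 0.8). The lists give no read numbers, so a difference in sequencing depth is not excluded.

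**Figure D3:**
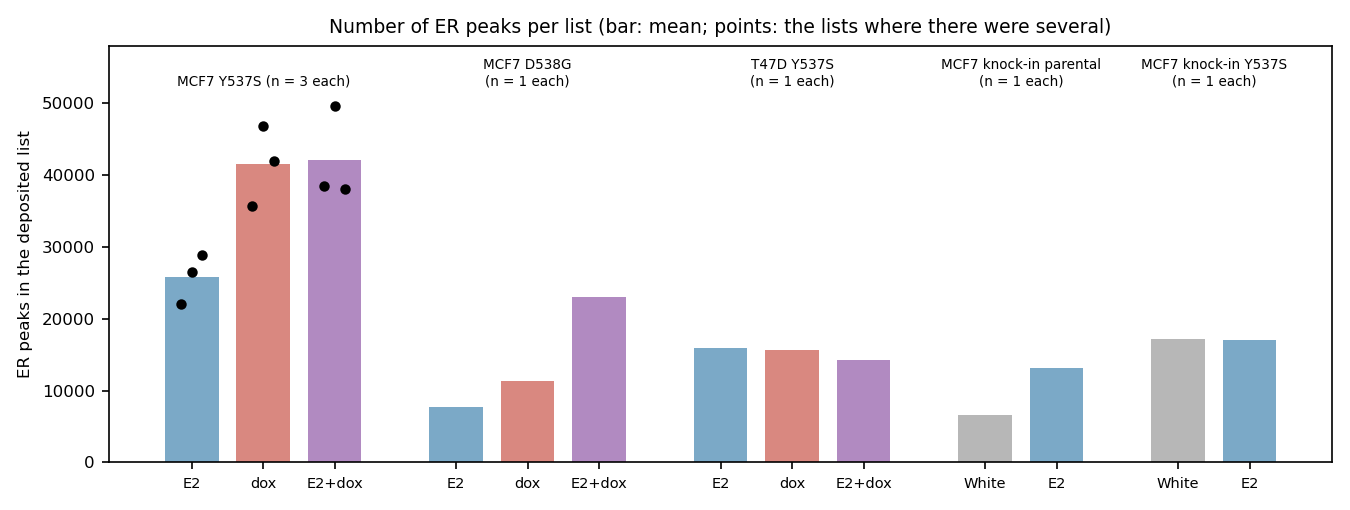
Number of peaks in each ER ChIP list (points) with the mean of the condition (bars), by line and condition. The 6 MCF7 Y537S lists with doxycycline lie between 35658 and 49568 peaks, above the 3 lists with estradiol alone, which lie between 22012 and 28872.

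Most consensus regions bound with estradiol in MCF7 Y537S were also bound with doxycycline. Of 20764 estradiol regions 17896 (86.2%) overlapped a doxycycline consensus region, and 1067 (5.14%) overlapped no doxycycline list. Of 35224 doxycycline regions 17786 (50.5%) overlapped an estradiol region and 11202 (31.8%) overlapped no estradiol list. Similar numbers of regions overlapped either way, so the shares of 86.2% and 50.5% differ with the sizes of the sets. Among the 21229 doxycycline regions present in 3 of 3 lists, 3111 (14.7%) overlapped no estradiol list. With both treatments there were 34170 regions, of which 28182 (82.5%) overlapped a doxycycline region and 18482 (54.1%) an estradiol region. Doxycycline peaks that overlapped an estradiol peak were stronger, with median fold enrichments of 10.4, 12.1 and 11.8 in the 3 lists against 6.19, 6.45 and 6.72 for those that did not. Among the strongest regions found in all 9 lists was chromosome 1, 1008549 to 1010087 (hg19), with fold enrichments of 224.0, 137.0 and 97.8 with estradiol and 129.0, 142.0 and 158.0 with doxycycline. Another lay on chromosome 12, 2904008 to 2905642, at 188.0, 209.0 and 97.8 with estradiol and 157.0, 169.0 and 160.0 with doxycycline. The strongest region found with doxycycline and in no estradiol list was chromosome 5, 14306584 to 14307174, with 41.2, 63.6 and 64.9 with doxycycline and 24.9, 49.7 and 54.3 with both. A region on chromosome 10, 37048303 to 37048733, had 37.1, 51.9 and 47.7 with doxycycline. No annotation of hg19 was used, so these regions are not assigned to genes.

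The other lines had 1 list per condition and no replicates, so their values carry no test. MCF7 D538G had 7748 peaks with estradiol, 11371 with doxycycline and 23022 with both. T47D Y537S had 15964, 15638 and 14306. In D538G 85.9% of the estradiol peaks overlapped a doxycycline peak (95% Wilson interval 85.1 to 86.7) and 58.7% the other way (57.8 to 59.6). These lists differ in length, and with the strongest peaks matched in number 72.8% overlapped either way. In T47D 60.2% of estradiol peaks overlapped a doxycycline peak (59.5 to 61) and 61.9% the other way (61.1 to 62.7). In the knock-in pair without estradiol, the parental line had 6584 peaks and the Y537S clone 17231. With estradiol the lists held 13133 and 17000. The parental lists share a title code and the clone lists share another, so a difference between these lines cannot be told apart from a difference between the codes. Of the parental peaks without estradiol 97.8% overlapped a peak of the Y537S clone without estradiol (97.4 to 98.2), and 37.1% of the clone's peaks overlapped one of the parental line (36.3 to 37.8). Of the parental peaks with estradiol, 82.5% overlapped a peak that the Y537S clone had without it (81.9 to 83.1), and 62.7% the other way (62 to 63.4). The knock-in lists differ in length: with the strongest peaks matched in number, 77.1% of the clone's peaks overlapped the parental list without estradiol and 78% the other way. For the clone without estradiol and the parental line with it, these were 73.1% and 73.5%.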

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

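Of the tests below, the test of a swap of libraries and the test of sequencing depth were chosen after their results had been seen, as was the alternative that left out the library concerned.

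All results here were marked because 2 effects under the same contrast differed in a test of the difference itself, either between cells without and with estradiol or between lines. The effect of doxycycline differed with and without estradiol in 1444 genes in MCF7 Y537S, 4422 in Y537N, 735 in D538G and 3335 in T47D Y537S. The mean interaction (log2) of the estrogen-raised list was -1.29, -0.902, -0.585 and -0.545 in these lines. For estrogen-lowered genes it was 0.706 in MCF7 Y537S and 0.536 in T47D. For ribosome biogenesis genes it was -0.326 in MCF7 Y537S and -0.683 in T47D, and for cell cycle genes in T47D -0.839. Between lines the white medium effect of doxycycline differed in 1997 genes for MCF7 Y537S minus D538G, 1169 for Y537S minus Y537N, 2140 for Y537N minus D538G and 4662 for MCF7 Y537S minus T47D. The mean difference of the estrogen-raised list was 0.56 for MCF7 Y537S minus D538G and 0.405 for Y537N minus D538G, and for that last pair -0.576 for the estrogen-lowered list.

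In 1 of 100 splits of the libraries, the real one, as many interactions were called in MCF7 Y537N as in the data (4422, highest other 2118). In D538G 9 of 100 splits gave as many as the real 735 (highest other 2477), in T47D 10 of 100 as many as 3335 (highest other 4903), and for Y537N minus D538G 6 of 100 as many as 2140 (highest other 2586), so this count does not exclude a random split of the samples for these. The splits with as large a result exchanged libraries in one doxycycline state alone, in 8 of 8, 9 of 9 and 5 of 5 cases. By the design, such a split of an interaction turns the effect of estradiol itself into an interaction, and for Y537N minus D538G it turns the difference between the lines at the same treatment into a difference of effects. Splits also put that effect or difference into the spread within groups, so they do not stand for data without an interaction. The count therefore cannot exclude a random split in Y537N either. Among the 75 splits that exchanged libraries in both states, the highest counts were 1 in Y537N, 1 in D538G, 2 in T47D and 0 for Y537N minus D538G.

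For comparisons of 3 libraries against 3, the 10 possible splits are too few for a share under 0.05, and the real split was the 1 with the most genes. Every other split mixes libraries of both groups, which puts an effect into the spread within groups and lowers the count. The low counts of the other splits therefore do not stand for data without an effect, and nothing is concluded from them. For doxycycline in white medium the real count and the highest other were 6508 and 0 in Y537N, 2492 and 1 in D538G, and 5886 and 0 in T47D. For estradiol they were 3817 and 1, 3927 and 0, and 6456 and 1. For doxycycline against estradiol they were 6288 and 0, 4364 and 1, and 6495 and 0. For doxycycline with estradiol they were 6121 and 0 in MCF7 Y537S, then 6411 and 1, 3806 and 0, and 6177 and 0. For full medium they were 6930 and 0 in MCF7 Y537S, 5162 and 21 in Y537N, and 5113 and 0 in D538G.

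Cell cycle genes were lower with doxycycline than with estradiol in white medium in all 4 lines, though only D538G kept the list call (adjusted p = 0.0117), and the others were adjusted p = 0.371, adjusted p = 0.151 and adjusted p = 0.104 with an estimated correlation in MCF7 Y537S, Y537N and T47D. A single library does not account for this, since the list mean stayed at or under -0.419 in every line with any library left out. Low values and the pseudocount do not either, since members with at least 10 FPKM had a median of at most -0.464 in every line, nor does scaling, since the list mean was at most -0.452 under both other scalings. Against white medium alone, doxycycline raised 0 and lowered 16 of 43 in MCF7 Y537S and raised 27 and lowered 2 in T47D, and with estradiol present it lowered 35, 31, 18 and 34 in the 4 lines. No biological explanation was tested, and an effect of doxycycline itself, or of the high level of receptor, stays open, since no line without a transgene was sequenced.

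Doxycycline and estradiol together changed estrogen-raised genes by less than the sum of their separate log2 changes. Members with at least 10 FPKM in white medium had a median interaction of at most -0.407 in every line, so low values and the pseudocount are not the cause. A single library is excluded as well, since the list mean stayed at or under -0.514. A common ceiling, at which joint treatment gives the level of the stronger single treatment, predicts a difference of 0 between these levels. For members raised by both treatments the median difference was 0.344 in D538G (SE 0.11, 28 members), the line farthest from 0. It was -0.148, 0.149 and 0.171 in MCF7 Y537S, Y537N and T47D, within the bounds set beforehand for a ceiling. Only D538G therefore argues against 1 ceiling for all lines, and its members share the same libraries, so they are not independent. By that rule a ceiling in the other lines is not argued against. Partial saturation of shared targets may remain as a hypothesis and was not tested.

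Replicate 2 of MCF7 Y537S in full medium with doxycycline stood apart in cell cycle genes, with a list mean of 4.98 against 4.39 and 4.46, and also in the integrated stress response list, with 5.02 against 5.78 and 5.82. A swap with a library without doxycycline is excluded, since its ESR1 was 13 times the highest of those. A share of cells without the transgene is excluded as well: other genes changed at least 2-fold lay at a median position of 0.933 of the way from the untreated to the other treated libraries (600 genes), against 0.202 for 39 called cell cycle genes. These sets are not those of the main comparison, which called 589 genes at 2-fold in all. Sequencing depth does not account for the deviation in cell cycle genes: the 15 libraries of other groups at least as shallow relative to their replicates deviated from them by at most 0.204 in this list, against 0.55 here. A biological difference between cultures, such as their density or growth state, was not tested and stays open.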

How the results depend on the processing

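The alternative without MCF7 Y537S full medium doxycycline replicate 2 was chosen after seeing the data, and 9 of 9 counts of called genes stayed within 1.5 times under it. Of all values under alternatives, 390 of 436 counts of called genes stayed within 1.5 times, 51 of 51 values of ESR1 kept their direction and call, as did 5823 of 6022 list results under the alternatives other than an estimated correlation and fry (81 lost and 118 gained a call) and 25015 of 26066 values of named genes (781 lost and 269 gained a call). Every count of called genes stayed within 1.5 times with median-of-ratios scaling, column-sum scaling, a pseudocount of 0.1, no filter on low values, and those last 2 together. Among values of named genes, the 1 that turned direction was that of KRT8, doxycycline in white medium, MCF7 Y537N: 3.99 (adjusted p = 0.22) with all libraries and -0.581 (adjusted p = 0.000251) without white medium replicate 3, where KRT8 is listed at 0, in a range of -0.581 to 6.27 over left-out libraries. KRT18, listed at 0 there as well but not among the genes named for that comparison, also turned direction. It went from 3.16 (adjusted p = 0.291) to -1.04 (adjusted p = 1.83e-07) without that library. The tests of peak numbers cannot pass 0.05 with or without the blocks of ChIP pairs, as their smallest possible p is 0.25 and 0.1. A planned minimum of CPM coincides with the filter used. The planned DESeq2 test and the gene-to-site comparison with its alternative distances and matched genes were not run, the first because the values are not counts. With 2 libraries in a group, leaving 1 out leaves a single library, assumed to vary like the other groups.

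Requiring an absolute log2 change of 1 leaves fewer genes by its construction. In the order MCF7 Y537S, Y537N, D538G, T47D the counts were 691, 649, 137 and 645 for doxycycline in white medium, 231, 178, 148 and 222 for estradiol, 769, 559, 164 and 551 for doxycycline against estradiol, 700, 743, 157 and 695 with estradiol present, 589, 286, 199 and 266 in full medium, and 180, 249, 39 and 174 for the interaction. For the line differences they were 325 (MCF7 Y537S minus D538G), 143 (Y537S minus Y537N), 144 (Y537N minus D538G) and 1058 (MCF7 Y537S minus T47D).

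For the other moves the cause was not tested, unless stated. A fit of only the compared libraries gave 1608 genes for doxycycline in white medium in D538G and 730 for Y537S minus Y537N, and a fit of all RNA libraries 2319 for the interaction in MCF7 Y537S. Leaving out libraries, which also means fewer samples, gave 1558 (without white medium replicate 3) to 3026 for estradiol in MCF7 Y537S, 539 to 1533 for its interaction (lowest without white medium replicate 3, and 811 without doxycycline replicate 3), 368 (without estradiol replicate 1) to 1166 (without doxycycline replicate 3) for the interaction in D538G, 2245 (without doxycycline replicate 3) to 3656 for full medium in T47D, and 617 (without MCF7 Y537S doxycycline replicate 2, and 684 without its white medium replicate 1) to 1697 for Y537S minus Y537N. Genes shared in direction with doxycycline in T47D were 2967, and 1558, 1816 and 1891 with the estradiol effect of MCF7 Y537S, Y537N and D538G.

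Of 24 comparisons within lines, the number with a list call went with an estimated correlation from 17 to 8 for estrogen-lowered, 21 to 6 for cell cycle, 16 to 0 for integrated stress response, 8 to 0 for mitochondrially encoded mRNAs, 5 to 0 for glycolysis and hypoxia, 10 to 1 for cholesterol synthesis, 8 to 0 for unfolded protein response, 16 to 5 for ribosome biogenesis, 13 to 0 for interferon-stimulated, 1 to 0 for epithelial and luminal, 2 to 0 for mesenchymal, 7 to 1 for basal epithelial and 1 to 0 for nuclear receptor targets. With fry, which does not compare a list with other genes, there were 17 for glycolysis and hypoxia, 15 for unfolded protein response, 12 for epithelial, 16 for mesenchymal, 16 for basal, 18 for nuclear receptor targets, and 4 for fibroblast and 5 for immune markers, from 0 each. The epithelial list had 2 with column sums, 2 with no filter, 2 with no filter and a pseudocount of 0.1, 3 with only compared libraries and 0 with all in one fit. The mesenchymal list had 0 with no filter, 0 with no filter and a pseudocount of 0.1 and 1 with all in one fit, the basal list 4 with all in one fit, and nuclear receptor targets 2 with median-of-ratios scaling and 2 with only compared libraries.

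Consensus regions present in 3 of 3 lists, fewer by construction, numbered 21229 with doxycycline and 17566 with both. Of estradiol regions 291 overlapped no doxycycline list, 11997 were shared with both treatments and 122 overlapped no list of both. Of doxycycline regions 3111 overlapped no estradiol list, 15473 were shared with both treatments and 118 overlapped no list of both. Of regions with both treatments 11918 were shared with estradiol, 1671 overlapped no estradiol list, 15431 were shared with doxycycline and 97 overlapped no doxycycline list. Between single lists, a larger required overlap, 0.5 of the peak, is stricter by construction. The percentage with it, then with the strongest peaks matched in number, was 59.7 (T47D doxycycline in estradiol, larger overlap), 55.9 and 61.1 (estradiol in doxycycline), 67.9 and 67.1 (both in estradiol), 58.3 and 66.6 (estradiol in both), 83.3 and 81.1 (both in doxycycline), and 76.5 and 81.1 (doxycycline in both). In D538G it was 57.3 and 72.8 (doxycycline in estradiol), 84.4 and 72.8 (estradiol in doxycycline), 28.6 and 73.7 (both in estradiol), 74.4 (estradiol in both, matched), 43.9 and 82.3 (both in doxycycline) and 83.2 (doxycycline in both, matched). In the knock-in pair it was 42.9 and 74.2 (parental with estradiol in without), 75 (parental without in with, matched), 32.3 and 77.1 (Y537S in parental), 78 (parental in Y537S, matched), 60.4 and 73.1 (Y537S in parental with estradiol), 81.3 and 73.5 (parental with estradiol in Y537S), 77 (Y537S with estradiol in without, larger overlap) and 75.7 (without in with, larger overlap). Read depth is unknown for both assays, so how far it limits weakly expressed genes and weak peaks cannot be given.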

Other observations

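Several lists not described so far moved with doxycycline in white medium. In T47D, 14 of 19 glycolysis and hypoxia genes rose and 1 fell (adjusted p = 8.48e-05, and adjusted p = 0.166 with an estimated correlation), among them PFKFB3, which makes an activator of glycolysis, from 28.1 to 88.4 FPKM, and VEGFA, an angiogenic factor, with a log2 change of 1.31. In the MCF7 lines that list was not called (adjusted p = 0.518, 0.242 and 0.282 in Y537S, Y537N and D538G). The integrated stress response list rose in T47D in 16 of 21 members with 1 falling (adjusted p = 6.16e-05, and adjusted p = 0.274 with an estimated correlation), CHAC1, which degrades glutathione, by 1.66, and was not called in MCF7 Y537S, Y537N or D538G (adjusted p = 0.684, 0.623 and 0.143). In T47D estradiol alone also raised the glycolysis and hypoxia list, in 11 of 19 members with 1 falling (adjusted p = 0.00028). It raised the integrated stress response list there in 15 of 21 with 1 falling (adjusted p = 2.21e-06). With an estimated correlation these were adjusted p = 0.117 and adjusted p = 0.18. All 13 mitochondrially encoded mRNAs rose in MCF7 Y537N (adjusted p = 0.000211, and adjusted p = 0.503 with an estimated correlation), such as MT-ND1, a subunit of complex I, from 1553 to 2241 FPKM. In D538G 2 of 13 rose (adjusted p = 0.00323, and adjusted p = 0.499 with an estimated correlation), in T47D 7 fell (adjusted p = 0.0388, and adjusted p = 0.521 with an estimated correlation), and in MCF7 Y537S 0 were called (adjusted p = 0.219). Of 15 unfolded protein response genes 8 rose in MCF7 Y537S (adjusted p = 0.00373, and adjusted p = 0.194 with an estimated correlation) and 4 rose and 1 fell in D538G (adjusted p = 0.0228, and adjusted p = 0.163 with an estimated correlation), while the list was not called in Y537N (7 rose and 3 fell, adjusted p = 0.0765) or T47D (4 rose and 2 fell, adjusted p = 0.525). Of 19 cholesterol synthesis genes 8 rose in MCF7 Y537S (adjusted p = 0.000857, and adjusted p = 0.3 with an estimated correlation). The list was not called in Y537N (4 rose and 5 fell, adjusted p = 0.71), D538G (3 rose and 1 fell, adjusted p = 0.0534) or T47D (3 rose and 8 fell, adjusted p = 0.0926). DHCR24 was among those that fell in T47D, from 270.2 to 124.0 FPKM.

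Lists of cell identity showed few shared changes with doxycycline in white medium. The epithelial and luminal list was called in no line (adjusted p = 0.898, 0.527, 0.253 and 0.103 in MCF7 Y537S, Y537N, D538G and T47D), and in Y537N its median was -0.116 and its mean 0.262, the latter raised by the keratins listed at 0 in 1 library. The basal epithelial list was not called either (adjusted p = 0.898, 0.623, 0.0735 and 0.667), with a median of -0.279 and a mean of 0.0202 in MCF7 Y537S. Against estradiol, 6 of 8 basal genes were lower with doxycycline in D538G (adjusted p = 0.00171). In MCF7 Y537S 6 were lower and 1 higher (adjusted p = 0.0291, and adjusted p = 0.371 with an estimated correlation), in Y537N 6 and 1 (adjusted p = 0.105), and in T47D 3 and 2 of 7 (adjusted p = 0.492). Of the mesenchymal list 4 of 5 fell and 1 rose in D538G (adjusted p = 0.0228, and adjusted p = 0.0971 with an estimated correlation), and in the other lines it was not called (adjusted p = 0.41, 0.264 and 0.376). Targets of other nuclear receptors were not called (adjusted p = 0.103, 0.623, 0.936 and 0.452), with a median of -0.11 and a mean of 0.265 in Y537N, although SGK1, a kinase induced by glucocorticoids, rose from 1.84 to 23.2 FPKM in MCF7 Y537S. Fibroblast markers had 3 tested members in Y537N (1 fell, adjusted p = 0.623) and T47D (2 fell, adjusted p = 0.132), and immune cell markers in T47D (1 rose, adjusted p = 0.453). Endothelial markers had too few tested members for a list test in each line.

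The next 4 genes rose with doxycycline in all 4 lines and had small or negative changes with estradiol. They were chosen after their values were seen, and no explanation was tested. ANXA9 had log2 changes with doxycycline in white medium of 4.17, 4.19, 1.79 and 1.1 in MCF7 Y537S, Y537N, D538G and T47D, and with estradiol of -0.17, 0.037, -0.21 and -0.12 (adjusted p = 0.12, 0.66, 0.116 and 0.156). FAM63A had 4.07, 3.32, 1.71 and 1.05 with doxycycline, and with estradiol 0.22 (adjusted p = 0.0217), 0.033, -0.14 and -0.57. HSD17B11 had 2.81, 2.01, 2.47 and 1.34 with doxycycline and -0.97, -0.56, -0.55 and -0.38 with estradiol, and NUDT9 2.15, 1.42, 1.67 and 0.53 with doxycycline and -0.47, -0.40, -0.31 and -0.23 with estradiol. In the GRCh38.p14 annotation ANXA9 and FAM63A lie beside each other on chromosome 1, and HSD17B11 and NUDT9 on chromosome 4, with 0 protein-coding genes starting between the members of each pair.

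The 6 MCF7 Y537N peak lists are given as values only, by title, since titles and attached lists disagree for 4 of them. The lists held 6942 and 23676 peaks with estradiol, 18356 and 13695 with doxycycline, and 48142 and 32130 with both.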
